A study of Mus musculus with 6 samples.

How the data were processed

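RNA was measured in cultures of primary bone marrow progenitors taken from female C57Bl/6 mice aged 12 weeks that had received fluorouracil, a drug that kills cycling marrow cells. Per the labels, the cells were transduced with retroviral constructs for Hoxa9 and Meis1 that carry fluorescent reporters and were grown with 15% fetal calf serum, interleukin 3, stem cell factor and interleukin 6. There were 3 arrays from miR-155 knockout cells and 3 from wild-type cells, grouped by the sample titles. The wild-type titles carry no distinguishing replicate number, so replicates were numbered in listing order and a number pairs no samples. The design text calls the experiments independent, and the labels do not say which animals or cultures they came from, so the p-values measure the spread between these arrays.

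Total RNA was labelled for whole-transcript Affymetrix arrays, per the labels' protocols. The deposited values are log2 expression values made by the robust multi-array average method (RMA) in Affymetrix Expression Console, per the submitters' processing notes. The version, the level of summary and the settings are not given in the sources used here. RMA corrects background, makes the arrays' distributions alike and summarises the probes of each feature, so a change in total RNA per cell cannot be seen and small differences can be compressed. The log2 scale was read from the values, which ran from 0.90 to 13.74. Scanner files were not used here, so detection calls were not made. The number of arrays limits the precision, and the median standard error of a difference was 0.10 on the log2 scale.

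Rows were named through the platform annotation matched to the table. Of 23332 rows, 14996 had 1 gene symbol, 1019 had several and 7317 were unnamed here. Of the single-symbol rows, 14941 matched the RefSeq gene table by gene identifier and 0 symbols needed an update. Where a gene had several rows, the row with the highest mean over all arrays was used, which left 14860 genes tested and 8472 rows unused. No row was named Mir155 or Mir155hg, so the level of the deleted gene was not analysed here. No transcript sequence was used, so genes with a miR-155 seed site were not tested.

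Knockout was compared with wild type in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, no trend, not robust, no filter on low values). Adjusted p-values are Benjamini-Hochberg over all genes, two-sided, with a threshold of 0.05. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so single genes were tested only with the model that shares the spread across genes. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over the 23 lists, whose members were fixed from general knowledge before the data were examined. A further list of sex-linked genes served as a label check. The olfactory receptor genes, which these cells are not thought to use, gave a background level by their 95th percentile, and 9968 genes, 67.1%, had a mean above it.

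Genes were named by a rule fixed before the data were examined. The rule takes Hoxa9 and Meis1, then per direction up to 10 genes past the adjusted threshold with no overlap between the groups. It fills each direction to 10 with genes at an unadjusted p under 0.05, an absolute log2 difference of at least 0.58 and no overlap, by size of difference. Predicted genes, olfactory and vomeronasal receptors and small RNA genes were left out, 17 on the higher side and 14 on the lower. Of each list, up to 4 members with the smallest p could be named.

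Alternatives fixed before the data were examined were median centring, a further quantile normalisation, array weights and filters at the 40th and 50th percentiles of level. They also included mean rows per gene, all rows, trend and robust variance models, other thresholds, an estimated correlation, fry, camera on ranks and leaving out each array. The grouping of the arrays on the first principal component as a block, alone and with the filter at the 50th percentile, was added after seeing the data. So were 3 further gene groups and 10000 random lists matched on level for each list. Most of the settings had been run once in an exploratory pass before the final computation. The fit was tested on simulated data with 14860 genes in 20 runs, 200 of them changed, with independent noise. It recovered 46.5% of genes changed by 0.5 on the log2 scale, 84.1% at 1, 95.8% at 1.5 and 98.2% at 2, with 5.35% false calls. These shares do not carry over to data in which few genes change, since the adjusted threshold is then stricter. In the same simulations camera called 0.05 lists on average with no effect, a figure that does not apply where genes vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.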

Results

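Messenger RNA levels were compared between mouse bone marrow progenitor cultures with and without miR-155, a microRNA of blood cells that lowers the mRNAs it pairs with. All cultures had been transduced with retroviral vectors carrying Hoxa9 and Meis1, a homeobox gene pair whose joint expression immortalises myeloid progenitors. The 2 groups were 3 arrays from miR-155 knockout cells and 3 arrays from wild-type cells, described in the design as independent experiments. The comparison asks which transcripts differ when Hoxa9 and Meis1 act in progenitors that lack miR-155. Each array gave 23332 values on a log2 scale, of which 1 row per gene was used for 14860 named genes. The median of all rows lay between 6.55 and 6.66 on the 6 arrays and the highest value between 13.64 and 13.74.

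Hoxa9 and Meis1 were among the brightest genes and did not separate the genotypes. Hoxa9 had a log2 level of 13.19 ± 0.06 (SD, n = 3) in the knockout and 13.27 ± 0.04 (SD, n = 3) in the wild type. The difference was −0.07 with a standard error of 0.07 (limma, adjusted p = 0.881). Meis1 stood at 11.73 ± 0.07 (SD, n = 3) against 11.80 ± 0.08 (SD, n = 3), a difference of −0.07 with a standard error of 0.08 (limma, adjusted p = 0.907). Whether these rows read the vector transcript, the endogenous transcript or both is not given in the sources used here. No row carried the name Mir155 or Mir155hg, so the genotype labels were not checked against the deleted gene. The Y-linked genes Eif2s3y and Kdm5d lay at 2.34 and 3.97 in the knockout and at 2.33 and 3.93 in the wild type. These levels were below 5.98, the 95th percentile of 718 olfactory receptor genes, and the labels name female donors.

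The arrays did not group by genotype on the main axis of variation. The first principal component held 37.21% of the variance and placed knockout 1, knockout 2 and wild type 2 on one side, with knockout 3, wild type 1 and wild type 3 on the other. The second component held 23.71%, with scores of 5.46, 2.48 and 17.29 for the knockout arrays and −5.55, −7.95 and −11.74 for the wild-type arrays. Over all rows, the correlation across rows averaged 0.983 for the 6 pairs of arrays of one genotype and 0.984 for the 9 pairs of different genotype. Over the tested genes these averages were 0.9936 and 0.9931, and over genes above the median level 0.9878 and 0.9851. Rows are not independent replicates, and no 2 arrays held identical values.

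**Figure D1:**
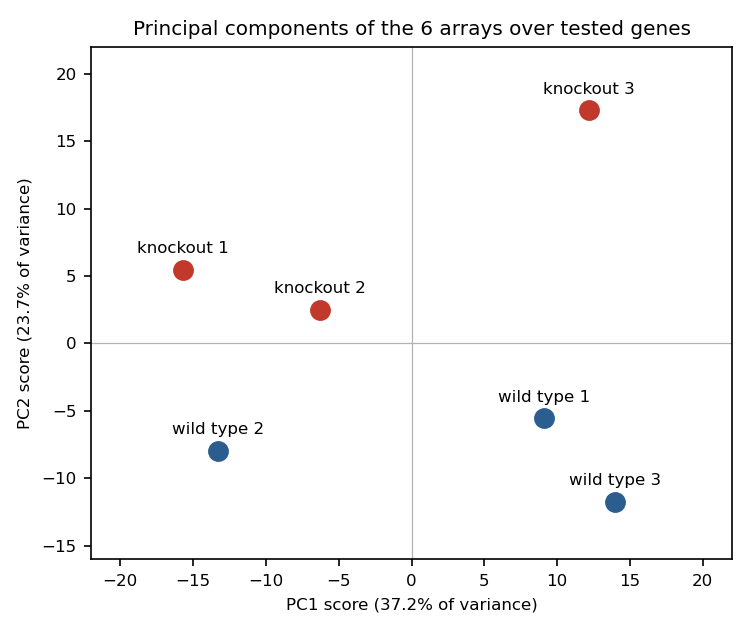
Scores of the 6 arrays on the first principal component (37.21% of variance, x axis) and the second (23.71%, y axis) over all tested genes, with red points for miR-155 knockout and blue points for wild type. Knockout and wild-type arrays mix along the first component and lie apart along the second.

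After adjustment over all genes, 4 genes were lower in the miR-155 knockout and 0 were higher, against 265 higher at an unadjusted p under 0.05. Tnfrsf9, a costimulatory receptor of the TNF receptor family, had a log2 level of 8.91 ± 0.18 in the knockout and 10.07 ± 0.11 in the wild type (SD, n = 3 each). This was a 2.24-fold lower level, with a log2 difference of −1.16 and a standard error of 0.11 (limma, adjusted p = 0.0378). Rcn3, a calcium-binding protein of the endoplasmic reticulum, was 2.04-fold lower, at 8.38 ± 0.08 against 9.41 ± 0.12 (SD, n = 3 each; limma, adjusted p = 0.0284). Vat1l was 1.94-fold lower, at 6.72 ± 0.07 against 7.68 ± 0.07 (SD, n = 3 each; limma, adjusted p = 0.0252). Capn11, a calpain protease gene, was 2.37-fold lower, at 4.65 ± 0.09 against 5.89 ± 0.12 (SD, n = 3 each; limma, adjusted p = 0.0252), although both levels lay below the olfactory receptor percentile of 5.98. Every knockout array was below every wild-type array for these 4 genes. With any 1 of the 6 arrays left out none of the 4 passed, the adjusted p reaching 0.258, while the log2 differences stayed between −1.29 and −0.92. With the grouping of the arrays on the first principal component in the model, a setting chosen after seeing the data, Capn11 (adjusted p = 0.00926) and Vat1l (adjusted p = 0.0406) passed again. Rcn3 (−1.04 with a standard error of 0.0902, against −1.03 with 0.0887) and Tnfrsf9 (−1.17 with 0.117, against −1.16 with 0.109) no longer passed (adjusted p = 0.0529 and 0.0847). Their differences moved by at most 0.02, and the standard errors rose while the model left fewer degrees of freedom. Under the same setting Fcer1a was higher (1.16, adjusted p = 0.0453) and Pcdh7, named after its value was seen, was lower (−0.913, adjusted p = 0.0466), against 0.98 and −0.79 without it. Over all 23332 rows, named or not, limma called 0 rows, with 1294 at an unadjusted p under 0.05.

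Further genes differed by at least 1.5-fold, with no overlap between the groups, but did not pass the adjusted test. On the lower side in the knockout, Csn2, which encodes beta-casein, had the largest difference of these, at 8.78 ± 0.21 against 10.15 ± 0.23 (SD, n = 3 each), a log2 difference of −1.37 (limma, adjusted p = 0.0725). Aldh1a3, an enzyme of retinoic acid synthesis, differed by −0.91 (adjusted p = 0.0945), Gpx8 by −0.95 (adjusted p = 0.421) and Tgm2, a transglutaminase, by −0.84 (adjusted p = 0.168). On the higher side, Fcer1a, the alpha chain of the high-affinity IgE receptor, stood at 9.29 ± 0.36 against 8.31 ± 0.30 (SD, n = 3 each), a log2 difference of 0.98 (limma, adjusted p = 0.392). Scin, an actin-severing protein, differed by 0.91 (adjusted p = 0.115), and Tph1, the rate-limiting enzyme of serotonin synthesis outside the brain, by 0.83 (adjusted p = 0.296). Maob, a monoamine oxidase, differed by 0.79 (adjusted p = 0.0731), Kif21a by 0.74 (adjusted p = 0.0893), Serpinb10 by 0.72 (adjusted p = 0.403) and Ptprk by 0.72 (adjusted p = 0.168). Mageb16, Txn1 and Magea4, with differences of 0.99, 0.96 and 0.94, lay below the olfactory receptor percentile in both groups, as did Krtap5-4 at −1.03 and Defb5 at −0.85.

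**Figure D2:**
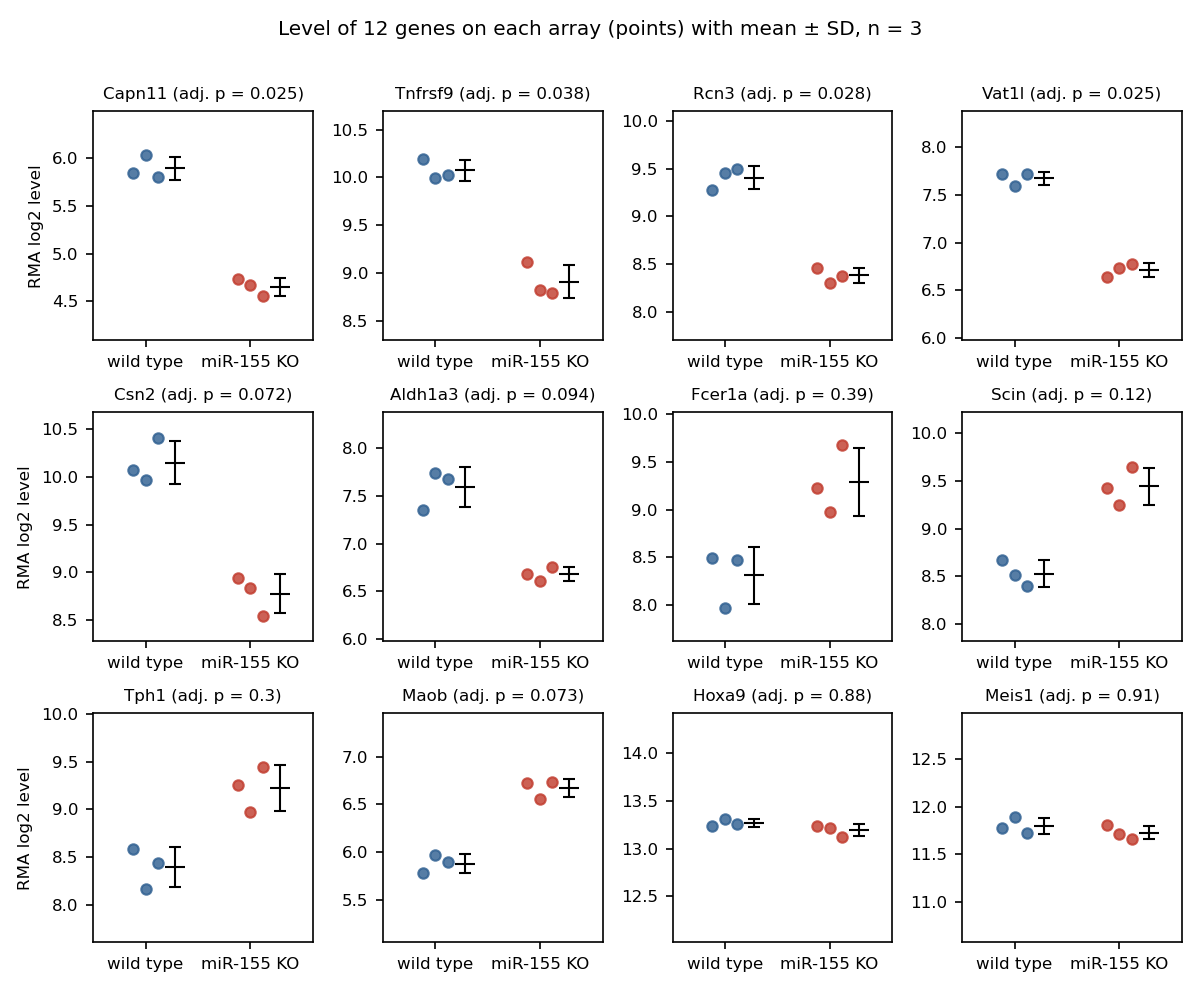
Log2 level (y axis) of 12 genes on each of the 3 wild-type arrays (blue points) and 3 miR-155 knockout arrays (red points), with mean ± SD beside the points and the adjusted p of the limma test in each title. Capn11, Tnfrsf9, Rcn3 and Vat1l pass the adjusted test, while Hoxa9 and Meis1 differ by −0.07 each.

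Across all genes, 12 passed at an adjusted p under 0.1, 2 higher and 10 lower in the knockout. At an unadjusted p under 0.05 there were 1074 genes, against 743 that chance gives when genes are independent. Of these, 265 were higher and 809 lower, a share of 24.7% higher. That share was 35.3% after each array was centred on its median and 45.8% after a further quantile normalisation, so the excess of lower genes depended on the scaling. The median difference of all genes was −0.03 on the log2 scale. In 1980 genes, 13.3%, the 3 knockout arrays did not overlap the 3 wild-type arrays, where chance gives 10%.

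Of 23 gene lists fixed before the data were examined, 6 passed a competitive list test (camera with a preset correlation of 0.01), 3 higher and 3 lower in the knockout. With the correlation between members estimated from the data, 0 of the 23 passed, with 1 list at an unadjusted p under 0.05. The rotation test fry, which asks whether a list's genes move 1 way on balance, also called 0 lists, with 4 at an unadjusted p under 0.05. No member of any list passed the limma test adjusted over all 14860 genes, so members are given as values and as counts adjusted over the list alone.

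Reported targets of miR-155 lay slightly higher in the knockout. The median log2 difference of the 44 measured targets was 0.05, with 32 above 0 and 12 below (camera, adjusted p = 5.5e-05; adjusted p = 0.637 with an estimated correlation). Adjusted over the list alone, 2 targets were higher and 1 was lower, against 8 higher and 2 lower at an unadjusted p under 0.05. The higher pair was the zinc finger gene Zfp652, at 8.78 ± 0.06 against 8.40 ± 0.04, and the BMP signal transducer Smad5, at 8.61 ± 0.01 against 8.30 ± 0.04 (SD, n = 3 each). The transcription factor Ets1 was lower, at 6.57 ± 0.04 against 7.08 ± 0.16 (SD, n = 3 each). Some of the best known targets were chosen for mention after their values were seen. Inpp5d differed by −0.01 with a standard error of 0.08, Spi1 by 0.005 with 0.12, Cebpb by −0.04 with 0.09 and Socs1, a suppressor of cytokine signalling, by −0.19 with 0.10. Jarid2 and Trp53inp1, also chosen after their values were seen, were higher by 0.36 with a standard error of 0.10 and by 0.46 with 0.13. The list median was 0.01 without knockout 1, 0.02 without wild type 3, 0.08 without wild type 2 and 0.10 without knockout 3. It was 0.09 with array weights, and 0.01 (camera, adjusted p = 0.0226; adjusted p = 0.571 with an estimated correlation) with the array grouping in the model.

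Megakaryocyte and platelet markers had a median difference of 0.18, and 11 of 12 measured members were above 0 (camera, adjusted p = 2.15e-05; adjusted p = 0.426 with an estimated correlation). Adjusted over the list alone, 2 were higher. Selp, the platelet adhesion molecule P-selectin, stood at 8.05 ± 0.10 against 7.45 ± 0.03, and the platelet chemokine precursor Ppbp at 10.30 ± 0.10 against 9.81 ± 0.13 (SD, n = 3 each). Nrgn, the 1 member below 0, differed by −0.31. With 1 array left out the median ran from 0.10 (without wild type 3) to 0.19, and the list passed each time at the preset correlation. The median was 0.17 with the array grouping in the model (camera at the preset correlation, adjusted p = 2.1e-05).

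Glycolysis and hypoxia genes had a median difference of −0.18, with all 16 measured members below 0 (camera, adjusted p = 0.0002; adjusted p = 0.637 with an estimated correlation). Of the 21 fixed members, Gapdh, Pgk1, Pgam1, Eno1 and Ldha had no row among the tested genes, so nothing was read for these glycolysis genes. Adjusted over the list alone, 1 member was lower, the hypoxia-induced carbonic anhydrase Car9, at 7.82 ± 0.25 against 8.39 ± 0.07 (SD, n = 3 each). Egln1, an oxygen-sensing prolyl hydroxylase, differed by −0.43, and the phosphofructokinase gene Pfkl by −0.23. The list did not pass without knockout 3 (median −0.09, adjusted p = 0.133). With the array grouping in the model the median was −0.24 (camera, adjusted p = 7.91e-06; adjusted p = 0.653 with an estimated correlation).

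The other 3 lists that passed were cell type markers, and each lost its call without single arrays. Eosinophil markers had a median of −0.45 with 6 of 7 members below 0 (camera, adjusted p = 0.0431; adjusted p = 0.637 with an estimated correlation). Of the 7, 4 lay below the olfactory receptor percentile in both groups. The granule protein genes Epx and Prg2 differed by −0.78 and −0.55, and 0 members passed when adjusted over the list alone, against 3 at an unadjusted p under 0.05. This list failed without knockout 1 (−0.28, adjusted p = 0.136), knockout 2 (−0.51, adjusted p = 0.09), wild type 1 (−0.32, adjusted p = 0.171) or wild type 2 (−0.39, adjusted p = 0.132). Stromal and endothelial markers had a median of −0.07 with 15 of 17 below 0 (camera, adjusted p = 0.0258; adjusted p = 0.637 with an estimated correlation). Of the 17, 8 lay below the olfactory receptor percentile in both groups. Adjusted over the list alone, 2 were lower, the PDGF receptor Pdgfrb by −0.34 and Pecam1, an adhesion molecule that blood cells also carry, by −0.36. This list failed without knockout 1 (−0.02, adjusted p = 0.0959), knockout 2 (−0.06, adjusted p = 0.122), wild type 1 (−0.05, adjusted p = 0.0838) or wild type 3 (−0.05, adjusted p = 0.05001), and its median was −0.16 without knockout 3 and −0.14 without wild type 2. Neutrophil granule and granulocyte markers had a median of 0.03 with 13 of 22 above 0 (camera, adjusted p = 0.0431; adjusted p = 0.637 with an estimated correlation). Mpo and Mmp8 differed by 0.24 and 0.40 and Lcn2 by −0.34, and 0 members passed adjusted over the list alone, against 4 in all at an unadjusted p under 0.05. The neutrophil median turned to −0.01 without knockout 2 (adjusted p = 0.26) and to −0.01 without wild type 3 (adjusted p = 0.716), and the list also failed without knockout 3 (0.04, adjusted p = 0.0962) or wild type 2 (0.06, adjusted p = 0.0831). With the array grouping in the model the medians were −0.42 for eosinophil (adjusted p = 0.214), −0.01 for stromal (adjusted p = 0.236) and 0.01 for neutrophil markers (adjusted p = 0.0895).

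**Figure D3:**
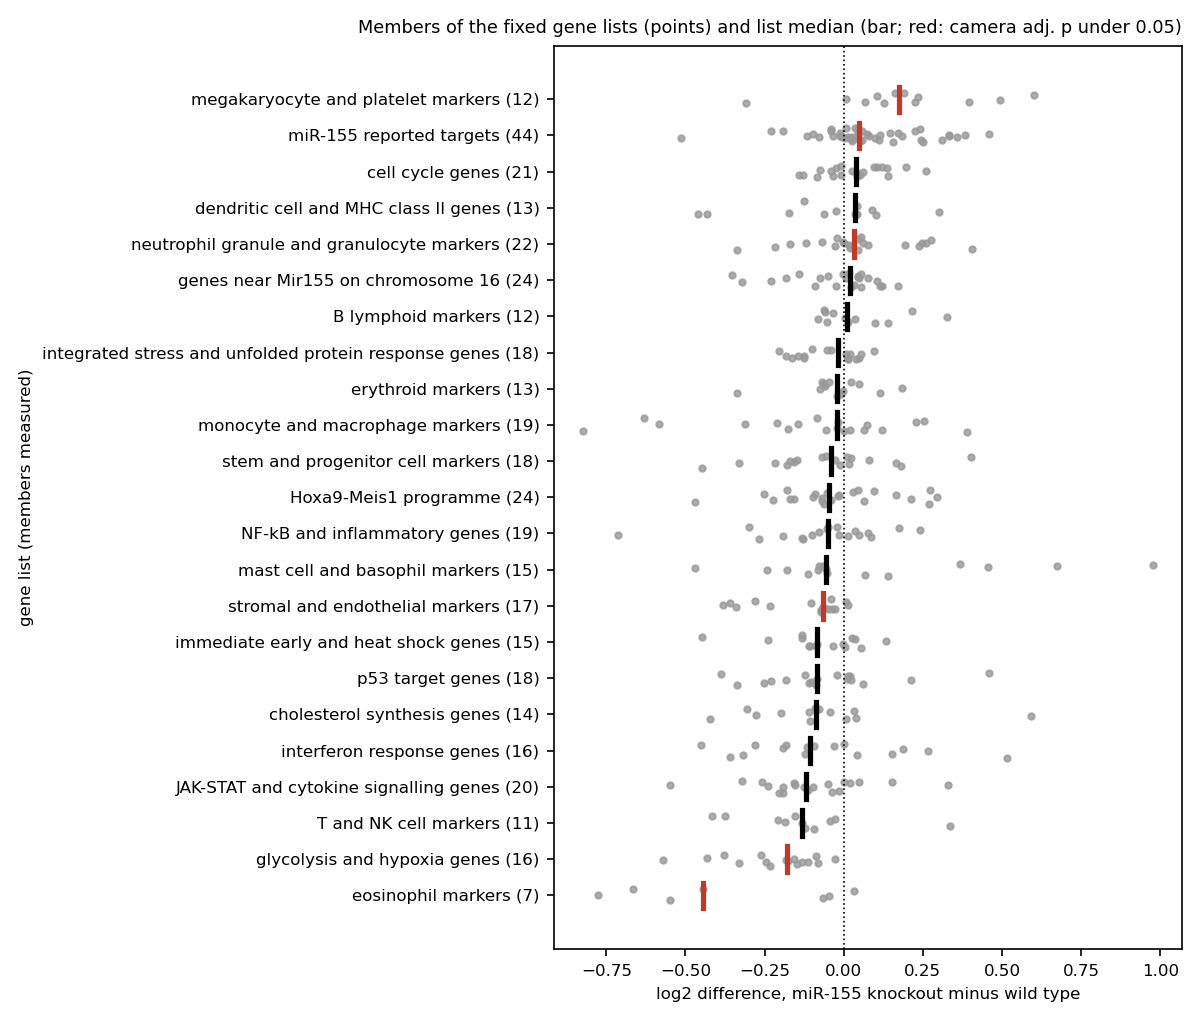
Log2 difference between miR-155 knockout and wild type (x axis) for the measured members (grey points) of each of 23 gene lists (y axis, number measured in brackets), with the list median as a bar, red where the camera test with a preset correlation passed. With an estimated correlation 0 of the 23 lists passed. All 16 measured members of the glycolysis and hypoxia list lie below 0, and 32 of 44 reported miR-155 targets lie above it.

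The other blood cell lists did not pass, although 3 of them did under some other settings. Monocyte and macrophage markers had a median of −0.02 (camera, adjusted p = 0.611), and Adgre1, the macrophage surface antigen F4/80, was the 1 member lower when adjusted over the list alone, at 9.70 ± 0.15 against 10.52 ± 0.07 (SD, n = 3 each). Without knockout 2 this list passed (median −0.11, adjusted p = 0.0395), while with all arrays and an estimated correlation its adjusted p was 0.888. Mast cell and basophil markers had a median of −0.06 but a mean of 0.09 and an upward test direction (camera, adjusted p = 0.158). Fcer1a was the 1 member higher over the list alone, Gzmb differed by 0.67 and Prss34 by −0.47. This list passed upward without knockout 2 (median 0.0036, adjusted p = 0.0395), without wild type 1 (median 0.0037, adjusted p = 0.0141), among genes above the median level (0.0681, adjusted p = 0.0391) and with the array grouping in the model (0.0281, adjusted p = 0.0226). With all arrays and an estimated correlation its adjusted p was 0.852. Of 11 measured T and NK cell markers, 6 lay below the olfactory receptor percentile in both groups. The 11 together had a median of −0.13 (adjusted p = 0.0818), with Thy1 at −0.42. They passed without knockout 3 (−0.148, adjusted p = 0.0203) or wild type 2 (−0.163, adjusted p = 0.0202), with array weights (−0.177, adjusted p = 0.0173) and after quantile normalisation (−0.116, adjusted p = 0.043), against 0.637 with an estimated correlation. B lymphoid markers had a median of 0.01 (adjusted p = 0.208). Erythroid markers had a median of −0.02 with an upward test direction (adjusted p = 0.845). Dendritic cell and MHC class II genes had a median of 0.04, a mean of −0.05 and an upward test direction (adjusted p = 0.875), and H2-Ab1 and H2-DMa differed by −0.46 and −0.43. Stem and progenitor cell markers had a median of −0.04 (adjusted p = 0.773), with the leukaemia-associated factor Hlf at −0.33.

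Among signalling and stress lists, JAK-STAT and cytokine signalling genes came closest to the threshold, with a median of −0.12 and 15 of 20 members below 0 (camera, adjusted p = 0.0521; adjusted p = 0.637 with an estimated correlation). Il2ra, the alpha chain of the interleukin-2 receptor, was the 1 member lower over the list alone, at 9.44 ± 0.22 against 9.99 ± 0.08 (SD, n = 3 each), and Pim2 and Cish differed by −0.32 and −0.24. This list passed without knockout 2 (−0.13, adjusted p = 0.0136) or wild type 3 (−0.12, adjusted p = 0.0085). It also passed after quantile normalisation (adjusted p = 0.043), with mean rows per gene (adjusted p = 0.0425) and at the filters on level (adjusted p = 0.0215 and 0.0218). Interferon response genes had a median of −0.10 (adjusted p = 0.24), and Oasl2, Ddx58 and Zbp1 were lower over the list alone, by −0.32, −0.36 and −0.45. Cholesterol synthesis genes had a median of −0.09 (adjusted p = 0.134), with Lss lower over the list alone by −0.42. They passed without knockout 1 (−0.142, adjusted p = 0.0308) and at the filters on level (−0.0904 at both, adjusted p = 0.0414 and 0.0391), against 0.637 with an estimated correlation. The medians were −0.05 for NF-kB and inflammatory genes (adjusted p = 0.773), −0.09 for p53 target genes (adjusted p = 0.557) and −0.08 for immediate early and heat shock genes (adjusted p = 0.739). They were −0.02 for integrated stress and unfolded protein response genes (adjusted p = 0.673) and 0.04 for cell cycle genes (adjusted p = 0.0901), which passed without wild type 2 (0.0835, adjusted p = 0.0292) and with array weights (0.0589, adjusted p = 0.0398), against 0.657 with an estimated correlation. The Hoxa9-Meis1 programme had a median of −0.05 with an upward test direction (adjusted p = 0.845), with Trib2 lower over the list alone by −0.47 and Mef2c at 0.27.

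Genes near Mir155 on chromosome 16 did not differ as a group. The median over 24 measured neighbours was 0.02, with a mean of −0.02 (camera, adjusted p = 0.739). Adjusted over the list alone 0 passed, against 3 at an unadjusted p under 0.05, namely Adamts1, Rbm11 and Nrip1, by −0.32, −0.35 and −0.23.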

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

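The array-grouping block was chosen after seeing the data, and the other settings before. No paired analysis was possible because the wild-type labels carry no distinguishing replicate number. The level of Mir155 and the seed-site test were not run under any setting, since no row or sequence was used for them. The cause was not tested for any shift below unless the setting removes genes or arrays. Of 1894 values for named genes, 1829 kept their direction and their side of the threshold, 28 lost the call, 36 gained one and 1 changed sign. The settings that change only the threshold reuse the values of the main fit, so theirs kept both by construction. Most named genes did not pass in the main fit, so the count that kept their side says little about stability. Of the gained calls, Adgre1 had 7, Csn2 6, Selp 4 and Aldh1a3, Scin and Maob 3 each, none of them with an array left out. Of 360 list medians, 277 kept both. With an estimated correlation, fry and camera on ranks the median is that of the main fit, so only the call could change there. With the sign kept, 31 lost the call and 16 gained one. The other 36 changed sign, and some of those also lost or gained the call.

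Against 4 genes called (0 higher, 4 lower), limma called 2 (2 lower) with each array centred, 16 (5 higher, 11 lower) with array weights, 12 (3 and 9) above the 40th percentile of level and 14 (3 and 11) above the median level. It called 9 (1 and 8) with a variance trend, 8 (1 and 7) with trend and robust, 12 (2 and 10) at an adjusted p under 0.1, and 0 over all rows (0 lower; 1294 at an unadjusted p under 0.05). With the array-grouping block it called 4 (1 higher, 3 lower; 2 shared with the 4), with Capn11 and Vat1l shared, Tnfrsf9 and Rcn3 lost, and Fcer1a and Pcdh7 gained. The block together with the median filter gave 50 (16 and 34; 3 shared), the largest count of any setting and one chosen after seeing the data. Leaving out 1 array gave 0 to 1 genes called (0 to 1 higher, 0 lower), with 739 to 1476 genes at an unadjusted p under 0.05. The 1 gene was Olfr218, higher without knockout 1, an olfactory receptor gene named after its value was seen.

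Lists called fell from 6 to 0 with an estimated correlation, 0 with fry and 3 with camera on ranks. These settings change only the test, so the miR-155 target median stays 0.0491, with an adjusted p of 0.637 with an estimated correlation and 0.473 with fry. Over all its alternatives the adjusted p ran from 2.46e-07 to 0.637. The adjusted p ran from 1.85e-06 to 0.426 for megakaryocyte markers, 1.67e-06 to 0.637 for glycolysis genes, 9.2e-05 to 0.637 for eosinophil, 0.00166 to 0.637 for stromal and 0.0013 to 0.716 for neutrophil markers.

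Medians near 0 changed sign. Quantile normalisation gave 0.0179 for erythroid and 0.0045 for stress response genes. Array weights gave −0.0561 for B lymphoid, −0.0124 for dendritic and −0.00056 for chromosome 16 genes. The filter at the 40th percentile gave 0.0095 for monocyte, 0.0011 for mast cell and −0.149 for dendritic genes, and that at the median 0.0196, 0.0681 and −0.172, with 0.0059 for stress response genes. The block gave 0.0281 for mast cell (adjusted p = 0.0226, upward) and −0.0039 for cell cycle genes. With 1 array left out the median ran from −0.0674 to 0.0352 for B lymphoid, −0.0116 to 0.0835 for cell cycle, −0.0423 to 0.0279 for dendritic, −0.0735 to 0.012 for erythroid, −0.0036 to 0.0423 for chromosome 16, −0.128 to 0.0417 for immediate early, −0.106 to 0.0545 for mast cell, −0.107 to 0.0284 for monocyte and −0.0125 to 0.0627 for neutrophil genes, and the difference of Rag2 from −0.0333 to 0.346.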

Other observations

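The tests chosen only after their results were seen were the count of genes over other splits, the correlation between the members of a list, and all tests of the array grouping. Standard errors in the tests of that grouping are widened for the members' correlation, except those within 1 side and the one of the cell mixture test. For the cell mixture, the single array and the 3 added gene groups, the decision bounds were also tightened after the values were seen, and each then had to be missed by more than a standard error. This reopened the cell mixture, the single array and STAT5, which the first bounds had rejected, and left the other 2 groups open as before. The remaining tests were set before their own values were known, but after the comparison had been examined, and the 3 added gene groups were picked because of genes seen in it.

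Further genes that passed at an adjusted p under 0.1 were named after their values were seen. Rspo1, a secreted activator of Wnt signalling, stood at 7.98 ± 0.11 in the knockout against 8.71 ± 0.11 in the wild type (SD, n = 3 each; limma, adjusted p = 0.086). The anion exchanger Slc26a6 and the receptor gene Glp1r differed by −0.75 and −0.65 (limma, adjusted p = 0.09 for both). Tnfrsf18, another costimulatory receptor, stood at 8.21 ± 0.15 against 8.84 ± 0.05 (SD, n = 3 each) and differed by −0.64 (limma, adjusted p = 0.16). Of 15 other measured genes named Tnfrsf, 13 were below 0, among them Tnfrsf1b by −0.36 and Tnfrsf8 by −0.28, and 0 passed over all genes, against 2 at an unadjusted p under 0.05. Of 11 collagen-processing genes, 10 were below 0, among them P4ha2 by −0.42 and the lysyl hydroxylase Plod1 by −0.39, while Fkbp9 differed by 0.26.

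Tnfrsf9, which passed, and Tnfrsf18, which did not, raise the hypothesis of a family-wide decrease of TNF receptor genes. The median of the 15 other members was −0.0994 (camera p = 0.0337, p = 0.216 with an estimated correlation), which leaves it open. Rcn3, which passed, and Gpx8 and Tgm2, which did not, raise the hypothesis that collagen-processing genes were lower as a group, and their median was −0.118 (camera p = 0.00879, p = 0.11 with an estimated correlation), which leaves it open too. Of 4 genes that STAT5 can induce, Tnfrsf9 passed, and Csn2, Il2ra and Cish did not (adjusted p = 0.0725, 0.402 and 0.709), and lower STAT5 output was weighed as a hypothesis. The 11 STAT5-inducible genes outside the fixed lists had a median of −0.0242, with 7 below 0, near the −0.0311 of all genes (p = 0.445 with an estimated correlation), and with members going both ways this decides nothing.

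Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few to give a share under 0.05. Every other split sets 2 arrays of a genotype against 1, so it keeps part of any genotype difference. The real split gave 4 genes past the adjusted threshold and the highest other split 1, so 1 of the 10 splits reached the real count. For lists called, the real split gave 6 and the highest other split 6, and 3 of the 10 splits reached that count. The split of knockout 1, knockout 2 and wild type 2 against the rest gave 3418 genes at an unadjusted p under 0.05, against 1074 for genotype, but 1 gene after adjustment. That split is the grouping along the first principal component, so its count restates the component and is no separate evidence.

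The labels name no batch that follows this grouping. Noise of dim rows could give such a split. Over genes above the median level, arrays of the same side, as assigned from dimmer genes alone, still correlated better by 0.0052 than arrays of different sides, only just above the between-side SD of 0.00513, which argues narrowly against dim rows as the whole source. A different mixture of cell types could also give it. The cell type list with the largest median difference between the sides was that of monocyte and macrophage markers, at −0.26 with a standard error over members of 0.0555, short of the 0.3 set for a clear shift by less than that error. As the sides were drawn from the same values, a cell mixture and an unrecorded batch cannot be told apart.

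The miR-155 target list is the one with a direct biological expectation, since loss of the microRNA is expected to raise its targets. A shift shared by genes of like level did not account for it, as the list median stood at percentile 99.96 of 10000 random lists matched on level. The array grouping pushes the list the same way, as 2 of the knockout arrays lie on its higher side. Relative to all genes the list differed by −0.1073 between the sides, where −0.241 would make the whole pattern, and the gap of 0.134 is within its standard error of 0.286. Most of that error is the 0.285 of the difference needed. It was widened for the members' correlation of 0.273 in the fit without the grouping, which was 0.0101 with the grouping in the model. The error thus partly holds the grouping under test, so this gap cannot decide. With the grouping in the model the list fell from 0.0803 to 0.0404 above all genes, with a standard error of 0.0307 (adjusted p = 0.571 with an estimated correlation). It was under its standard error without wild type 3 (0.0252 against 0.0316), knockout 1 (0.0287 against 0.0303) or wild type 2 (0.0409 against 0.0481). It was above it without wild type 1 (0.0674 against 0.0282), knockout 3 (0.0686 against 0.0445) or knockout 2 (0.0454 against 0.0396), so the grouping as the whole cause stays open. Variation of the target genes together between arrays may account for the call. After genotype was removed the members correlated by 0.273. This lay just above 0.256, the upper bound of the middle 95% of random lists matched on level. With the grouping in the model the estimated correlation was 0.0101, so this variation was not shown to be separate from the grouping. Relief from miR-155 stays a hypothesis.

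The glycolysis and hypoxia list met part of the same limit. Its median lay at percentile 0 of random lists matched on level, which argues against a shift shared by genes of like level. With all arrays, the array grouping as the whole cause is argued against too, as its estimate goes the other way. The list differed by −0.1414 between the sides relative to all genes, where 0.448 would make the whole pattern, a gap of 0.589 with a standard error of 0.341. The side difference itself did not pass (camera p = 0.363 with an estimated correlation), and without knockout 3 it was −0.028. The difference needed was computed from all arrays only, so the fits with 1 array left out cannot test this. What stays open is variation of these genes together and 1 array. The members correlated by 0.525 after genotype was removed, where that bound was 0.262, so such variation may account for the call. With the grouping in the model the estimated correlation was 0.535, and 0.0139 without knockout 3. Leaving out wild type 2 gives the same 0.0139 by construction. Either fit estimates the correlation only from knockout 1 against knockout 2 and wild type 1 against wild type 3. The fall from 0.535 therefore cannot be placed on either array, and such variation and 1 array were not told apart. Relative to all genes the median was −0.149, and without knockout 3 it was −0.0544 and the call ended (adjusted p = 0.133). This missed the bound set beforehand for a single-array cause, 1 part in 3 of the full value, by less than a standard error. With the grouping in the model the median was −0.212 with a standard error of 0.124. Without knockout 3 the difference in that fit rests on knockout 1 and knockout 2 against wild type 2 alone, and was −0.0358 with 0.0411. Within the side of knockout 3, wild type 1 and wild type 3, immediate early and heat shock genes lay at −0.311 and monocyte markers at −0.268 relative to all genes, beside −0.354 for this list. On the other side these were 0.0456, 0.0141 and −0.0358, the last being the value already given for the fit without knockout 3. Whether knockout 3 alone or the genotype drives the decrease cannot be told apart, since that side has 1 knockout array and the other shows a decrease within its standard error of 0.0374.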
